A study of Homo sapiens with 6 samples.

How the data were processed

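RNA was extracted from A549 cells with a spin-column kit and made into libraries with a SMARTer mRNA-seq kit, per the labels' protocols, 3 libraries with a control guide and 3 with a guide against H2AC19. A single table covers the series. Its values are FPKM computed by the authors before they were deposited, per the file headers, with 1 column per library, so replicates were not pooled. The aligner, the counting tool and the annotation are not given in the sources used here. Per the submitters' processing notes the genome builds were GRCm38 and mm10, which are mouse builds, whereas all 62700 gene IDs match a table of human Ensembl genes and 0 have the mouse prefix. The columns written sgNC were taken as sgControl and those written sgH2AC as sgH2AC19, with the number that follows as the replicate, and 0 columns of values were left unused. No pair of libraries held identical values.

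Depth was recovered from the table. Within a library the FPKM values of a gene are whole multiples of the value of 1 read, so the totals follow from the annotated gene lengths in GENCODE 29, in which 58207 of the IDs have an entry. With these totals 12869 of the 12871 genes tested gave whole reads in all libraries, within a tolerance of 0.001 reads, 3759 of them at the annotated length and the others at the smallest length that gave whole reads. The totals differ by a factor of 1.28 between the deepest and the shallowest library. Single reads were seen in 1028 to 1079 genes per library at the annotated length and 2 reads in 1775 to 1968. Whether mates were counted one by one was not tested. FPKM correct for gene length and depth but not for composition, and the 20 most abundant genes held 33.6% to 36.4% of the FPKM per library.

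Before the data were examined, a count test was planned, with limma on log2 values as the test to use if the table held normalised values. Since it holds FPKM, the second was used and the planned count test was not run. A fit on the recovered reads, with voom, was made only as an alternative. Genes with at least 1 FPKM in at least 3 libraries were kept and values were taken as log2(FPKM + 1). Then limma (3.58.1, R 4.3.3) with a mean-variance trend compared the groups, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Means and SDs are of FPKM over the 3 libraries of a group, and SEs are those of limma's fit. All adjusted p-values for single genes are from limma.

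In all 27 gene lists were fixed before the data were examined, from textbook knowledge, among them markers of endothelial cells, fibroblasts and leukocytes as cell types that a culture could hold. Each list's members were counted over all genes tested and adjusted over the list alone. Lists were tested with camera from limma at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 25 lists with at least 2 members measured. Of these 11 were called at the preset correlation, 0 with an estimated one (smallest unadjusted p 0.0847) and 8 with fry.

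The genes named in the text were chosen by a rule fixed beforehand. It takes H2AC19 and H2AC18, the 10 largest rises and 10 largest falls among called genes with separated groups, at least 1 FPKM in the higher group and a named symbol that is not of a pseudogene or clone. It also takes up to 4 called members of each list with the smallest adjusted p, and VEGFA. One name, RNU6-1005P, was among the 10 largest falls and was left out as a pseudogene-type name by a pattern added after it had been seen, which let CDCP1 in. List members outside the rule, such as PDGFC, TGFB2, EDN1, MMP2, MMP7, EGFL7 and CD14, were named after their values had been seen. Some genes that the rule takes are not reported here.

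The alternatives tried were median-ratio and upper-quartile scaling, voom on the recovered reads, all genes above 0 FPKM, a mean of at least 1 FPKM, the replicate number as a block, a pseudocount of 0.1, and leaving out each library in turn. Chosen after seeing the data was a fit without genes that hold either of the 3′ UTR words described among the observations or have no 3′ UTR to search. All 10 splits of the 6 libraries into 3 and 3 were fitted as well. For 3′ UTR words, log2 fold changes of 10532 genes with an annotated 3′ UTR of at least 50 bases in GENCODE 29 were corrected by a linear fit for 3′ UTR length, GC content and mean expression. Each word of 7 or 8 bases found in at least 30 genes was scored by a rank-sum z. For the held-out tests the leading 7-base word was chosen on odd-numbered or even-numbered chromosomes, among words in at least 15 genes there, and scored on the other set. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

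The steps were tested on simulated data. For sgH2AC19 against sgControl, over 12651 genes, the gene test recovered 82 of 97 tested genes given a log2 change of 0.5 and 96 of 96 given a change of 1, with 11 false calls among 189. Over 12871 genes the list test called 3 of 3 lists shifted by 0.2 and 0 of the others, on noise drawn independently for each gene. It therefore does not show how often the preset correlation gives false calls where genes vary together. In the real libraries a split other than the real one called 13 lists. Read recovery was exact for 100% of 500 simulated genes. The word test, over 10532 genes, ranked a word given a shift of 0.1 first in 10 of 10 runs.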

Results

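The series title puts H2AC19, a gene for a replication-dependent histone H2A, in the context of angiogenesis in lung adenocarcinoma. RNA was sequenced from A549, an established human lung adenocarcinoma line of epithelial origin, in 2 groups of 3 libraries. The sgControl libraries carry a control guide RNA and are labelled wild type, and the sgH2AC19 libraries are described as knockout derivatives. The deposited table gives FPKM (fragments per kilobase of gene length, scaled to the fragment total of the library) for 62700 human genes, of which 25762 were at 0 in all 6 libraries. Read totals recovered from the spacing of the values were 36255807, 39520141 and 40570759 for sgControl replicates 1 to 3, and 45738439, 35681162 and 37985593 for sgH2AC19 replicates 1 to 3. Genes encoded in the mitochondrial genome held 29.6% to 32.5% of the FPKM in each library.

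The targeted gene could not be followed. H2AC19 (ENSG00000288859) was listed at 0 FPKM in each of the 6 libraries, and so was its near-identical copy H2AC18 (ENSG00000288825). In GENCODE 29 (GRCh38) H2AC19, there named HIST2H2AA4, lies on chromosome 1 from 149851061 to 149851624 on the plus strand with 1 exon, and H2AC18, there named HIST2H2AA3, lies from 149842188 to 149842736 on the minus strand, also with 1 exon. The neighbouring histone genes H3C14, H3C15 and H4C14 were at 0 in all 6 libraries as well, and H4C15 was at 0 except for 0.0233 FPKM in sgH2AC19 replicate 1. The target therefore checks neither the knockout nor the labels, and the direction of every comparison rests on the labels alone.

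The comparison the design names is sgH2AC19 against sgControl. Of 12871 genes tested, 2967 changed (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p below the 0.05 threshold), 1545 of them up and 1422 down. Most changes were small, with a median size of 0.32 on the log2 scale among the genes called, and 49 genes changed at least 2-fold on the log2(FPKM + 1) scale, 30 up and 19 down. All 2967 called genes had the 3 libraries of one group above the 3 of the other, as did 43.2% of all genes tested, where chance gives 10%. The first principal component (53.7% of the variance) separated the groups, and the second (18.2%) set sgH2AC19 replicate 3, at −16.0, apart from replicates 1 and 2, at 8.09 and 8.32. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The count fell to 1663, 1513 and 1632 without sgControl replicate 1, 2 or 3, fell to 1965 without sgH2AC19 replicate 2, and was 3429 without sgH2AC19 replicate 3. It was 1553 (900 up, 653 down) over all 36938 genes above 0 FPKM in at least 1 library.

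**Figure D1:**
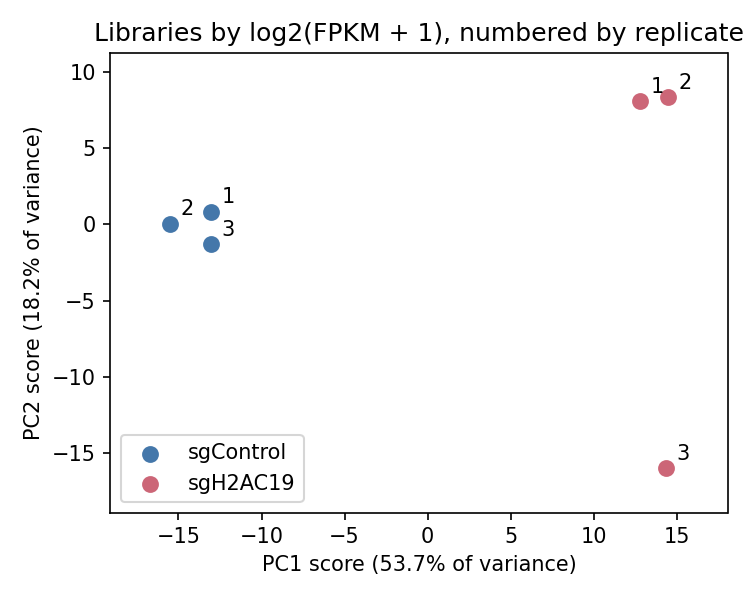
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), in units of the component score; each point is a library, coloured by group and numbered by replicate. The groups lie at opposite ends of the first component, and sgH2AC19 replicate 3 lies at −16.0 on the second.

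Among the genes that rose most were all members of the fibrinogen cluster on chromosome 4, which encode the 3 chains of the clotting protein. FGA (ENSG00000171560) went from 7.77 ± 0.617 FPKM in sgControl to 21.3 ± 2.09 in sgH2AC19 (SD, n = 3 each), a log2 fold change of 1.35 (SE 0.0824, limma adjusted p = 0.000271). FGG rose by 1.42 and FGB by 1.34. The largest rise was that of CPLX2 (ENSG00000145920), a regulator of vesicle exocytosis, from 5.91 ± 1.19 to 22.3 ± 1.32 FPKM (log2 fold change 1.76, SE 0.116, adjusted p = 0.000335). CLDN2, a tight junction protein, rose by 1.63, CYP1B1, a cytochrome P450, by 1.45, the galactosyltransferase gene B4GALT1 by 1.18, the cationic amino acid transporter gene SLC7A2 by 1.18 and SERPINI1 by 1.17. The 3′ UTRs of CYP1B1 and B4GALT1 hold the 7-base word TCGGAGA, picked because its genes stood highest, and genes with this word lay 0.176 (SE 0.0215) above the rest on the log2 scale. The 3′ UTR of CYP1B1 also holds CCTAAGA, which ranked 2 of 16318 words by the fall of its genes, after CTAAGAA. Genes with CCTAAGA lay at −0.104 and −0.108 against the rest in sgH2AC19 replicates 1 and 2 and at 9.5e-05 in replicate 3. CCTAAGA is held by 1057 of the 10532 genes searched and by 0 of the 10 largest falls. Whether either word moved any single gene was not tested.

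The genes that fell most were led by secreted cytokines, chemokines and a matrix-degrading enzyme. The interstitial collagenase gene MMP1 (ENSG00000196611) went from 4.16 ± 0.0625 to 0.561 ± 0.213 FPKM (log2 fold change −1.74, SE 0.104, adjusted p = 0.000271). The cytokine gene IL24 went from 6.42 ± 0.717 to 1.26 ± 0.777 (−1.78, SE 0.257, adjusted p = 0.0041). CXCL5 (ENSG00000163735), a neutrophil-attracting chemokine and the most abundant of these transcripts, went from 647 ± 29.3 to 239 ± 65.4 FPKM (−1.48, SE 0.187, adjusted p = 0.0026). It was at 166 FPKM in sgH2AC19 replicate 3 against 256 and 294 in replicates 1 and 2. Log2 fold changes were −1.62 for TMEM158, −1.41 for the chemokine gene CXCL3, −1.33 for the AP-1 transcription factor gene FOSL1, −1.18 for FA2H, −1.13 for BCL2A1 and −1.12 for CDCP1. Each of these 18 genes kept its call when any 1 library was left out, and its direction was fixed by the separated groups. The exception was MMP1, at 1 FPKM or more only in the sgControl libraries, which did not pass the filter without one of them.

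**Figure D2:**
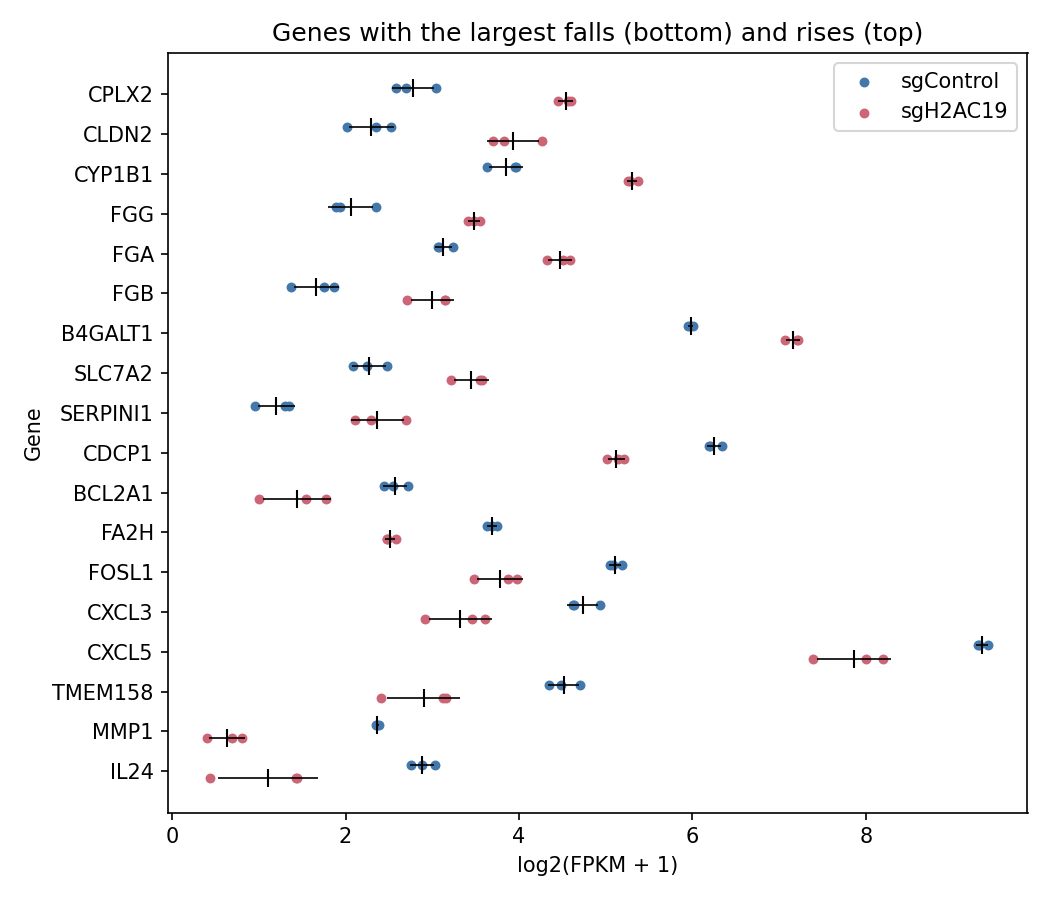
Each library's log2(FPKM + 1) for 9 of the genes with the largest falls and 9 of those with the largest rises, one row per gene; points are libraries, vertical ticks are group means and horizontal bars are 1 SD (n = 3). The 3 sgH2AC19 points lie on one side of the 3 sgControl points in each of the 18 rows, which the rule that chose the genes required.

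Some secreted factors that promote angiogenesis, the process the series title names, fell, and VEGFA was not called. Of 51 measured members 14 fell, 5 rose and 32 were not called, and 17 fell and 5 rose when adjusted over the list alone (camera with a preset correlation, adjusted p = 0.031, and adjusted p = 0.722 with an estimated correlation). Among the falls MMP1, IL1A and CSF2 passed the filter only through the sgControl libraries, so they could not have been called up. Besides MMP1, CXCL5 and CXCL3 the falls included the EGF-receptor ligand gene TGFA, from 5.87 ± 0.172 to 3.83 ± 0.265 FPKM (log2 fold change −0.51, adjusted p = 0.00182). The neuregulin gene NRG1, whose 3′ UTR holds the word CCTAAGA, went from 17.2 ± 0.06 to 12.9 ± 0.685 (−0.40, adjusted p = 0.0023). It was also low in sgH2AC19 replicate 3, at 13.6 FPKM against 12.5 and 12.4 in replicates 1 and 2. VEGFA (ENSG00000112715), the main vascular growth factor of hypoxic cells, was at 17.99 ± 2.67 and 18.5 ± 0.0694 FPKM (log2 fold change 0.04, SE 0.0929, adjusted p = 0.767), with a log2 fold change of −0.04 without sgControl replicate 1. PDGFC, TGFB2, EDN1, MMP2 and MMP7 rose, PDGFC furthest at 0.46. The call was also lost without sgControl replicate 1 (adjusted p = 0.0894), sgControl replicate 2 (0.112) or sgH2AC19 replicate 2 (0.0677).

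Genes for angiogenesis inhibitors moved both ways. Of 20 measured, 5 rose, 3 fell and 12 were not called, with the same counts when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.345). IGFBP4, which encodes a binding protein for insulin-like growth factors, went from 217 ± 10.7 to 457 ± 10.0 FPKM (log2 fold change 1.07, SE 0.0468, adjusted p = 8.9e-05). The guidance cue gene SEMA3A rose from 6.29 ± 0.134 to 9.13 ± 0.435 FPKM (0.47, adjusted p = 0.00149), and its 3′ UTR holds CCTAAGA. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, fell by 0.55 and lost its call when all genes above 0 FPKM were tested (adjusted p = 0.0599). With fry, which asks whether the members move one way on balance, the list passed (adjusted p = 0.0271).

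Some inflammatory genes fell in sgH2AC19. Of 30 measured genes of the NF-kB and inflammatory response list 14 fell and 2 rose, 18 and 2 when adjusted over the list alone (camera adjusted p = 0.000357, adjusted p = 0.722 with an estimated correlation, and fry adjusted p = 0.143). BIRC3, an inhibitor of apoptosis induced by NF-kB, went from 53.7 ± 3.48 to 26.7 ± 0.948 FPKM (log2 fold change −0.98, SE 0.0574, adjusted p = 0.000243). The exceptions were IL11, an IL-6 family cytokine gene, up from 4.29 ± 0.604 to 10.5 ± 0.837 FPKM (1.12, SE 0.0931, adjusted p = 0.00074), and the complement gene C3, up by 0.51. The list shares 6 of its called members with the pro-angiogenic list, CCL2, CSF2, CXCL3, CXCL5, IL1A and LIF, so the 2 lists are not independent. Of these, CSF2 and IL1A passed the filter only through the sgControl libraries and could not have been called up. Interferon-stimulated genes were not called as a list (3 up, 4 down of 37, the same adjusted over the list alone, camera adjusted p = 0.383), with IFITM2 up by 0.41 and TRIM25 at −0.49.

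Hypoxia and HIF target genes fell in part. Of 48 measured, 13 fell and 2 rose, 17 and 4 when adjusted over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.844 with an estimated correlation). ALDOC, which encodes an aldolase of glycolysis, went from 19.3 ± 2.10 to 9.94 ± 0.887 FPKM (log2 fold change −0.89, SE 0.0913, adjusted p = 0.00137). TPI1 and HK1 were at −0.23 and −0.22, and the collagen cross-linking enzyme gene LOXL2 at −0.41. The list's call was lost without sgControl replicate 2 (adjusted p = 0.066) and with fry (0.374). TPI1 lost its call without sgControl replicate 3 (0.0501), and HK1 without sgControl replicate 2 (0.0561) or 3 (0.059).

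Some genes induced by p53 fell in sgH2AC19. Of 41 measured, 11 fell and 2 rose, 12 and 2 when adjusted over the list alone (camera adjusted p = 0.0386, and adjusted p = 0.765 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, went from 72.2 ± 5.19 to 45.5 ± 2.38 FPKM (log2 fold change −0.65, SE 0.0641, adjusted p = 0.0012), and its 3′ UTR holds CCTAAGA. It was also low in sgH2AC19 replicate 3, at 48.1 FPKM against 43.3 and 45.1 in replicates 1 and 2. The stress cytokine gene GDF15 went from 78.1 ± 5.03 to 42.8 ± 8.22 (−0.87, SE 0.133, adjusted p = 0.00509). CD82 and the death receptor gene TNFRSF10A fell by 0.59 and 0.61. CD82 passed the filter only through the sgControl libraries. The list's call was lost without sgControl replicate 1 (adjusted p = 0.0894), sgControl replicate 2 (0.0777) or sgH2AC19 replicate 3 (0.238), and with fry (0.14).

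Some proliferation genes rose. In the DNA replication and S phase list 18 of 63 measured genes rose and 0 fell by limma (33 and 0 at an unadjusted p under 0.05), and 45 were not called. Adjusted over the list alone the counts were 26 and 0 (camera adjusted p = 3.7e-08, and adjusted p = 0.722 with an estimated correlation). GMNN, the replication licensing inhibitor geminin, went from 8.65 ± 0.458 to 11.7 ± 0.141 FPKM (log2 fold change 0.39, SE 0.0497, adjusted p = 0.00252). The licensing factor gene CDC6 went from 12.8 ± 0.364 to 16.5 ± 0.583 (0.34, adjusted p = 0.00358). In the G2/M and mitosis list 15 of 55 rose and 1 fell, 16 and 1 when adjusted over the list alone (camera adjusted p = 0.000396, and adjusted p = 0.722 with an estimated correlation). MYBL2, a transcription factor of the cell cycle, went from 20.01 ± 0.298 to 31.6 ± 0.957 FPKM (0.63, SE 0.042, adjusted p = 0.000336), and BIRC5 (survivin) rose by 0.56. The S phase list lost its call with fry (adjusted p = 0.0618), and the G2/M list with fry (0.14) and without sgH2AC19 replicate 3 (0.0561).

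Some histone genes other than the target rose. Only 4 of the 17 listed replication-dependent H2A genes were measured. Of these H2AC6 (16.99 ± 0.744 to 28.0 ± 5.83 FPKM, log2 fold change 0.67, adjusted p = 0.0157) and H2AC15 (0.639 ± 0.0952 to 1.61 ± 0.189 FPKM, 0.67) rose. H2AC15 was at 1 FPKM or more only in the sgH2AC19 libraries and passed the filter through them alone, so it could not have been called down. The count was 2, and 3 when adjusted over the list alone, with 3 higher and 0 lower by limma at an unadjusted p under 0.05 (camera adjusted p = 0.031, and adjusted p = 0.722 with an estimated correlation). H2AC6 was at 21.3 FPKM in sgH2AC19 replicate 3 and at 30.8 and 32.0 in replicates 1 and 2, and lost its call without sgControl replicate 2 (adjusted p = 0.0577) and when all genes above 0 FPKM were tested (0.0741). Of 10 other replication-dependent histone genes 5 rose, 7 when adjusted over the list alone, with 0 lower by limma in either count or at an unadjusted p under 0.05 (camera adjusted p = 0.000188, and adjusted p = 0.722 with an estimated correlation). As with H2AC15, a gene among those that rose passed the filter only through the sgH2AC19 libraries, so it could not have been called down. H2BC5 went from 6.90 ± 0.412 to 15.3 ± 2.40 FPKM (1.03, SE 0.107, adjusted p = 0.00143). Among 29 genes for histone variants and chaperones 8 rose and 1 fell, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.722 with an estimated correlation). The centromeric histone gene CENPA rose by 0.49 and the chaperone gene NASP by 0.41. CENPA is also on the G2/M list and NASP on the S phase list, so these lists are not independent. Values of histone genes are uncertain, since close copies share reads. How fully these mRNA-seq libraries captured replication-dependent histone transcripts was not tested. The H2A list lost its call in 4 of the 6 fits without 1 library (adjusted p up to 0.205), when all genes above 0 FPKM were tested (0.0643) and without the genes that hold either 3′ UTR word or have no 3′ UTR to search (0.0966), and the variant list lost it without sgControl replicate 2 (0.066). Genes neighbouring the target on 1q21 were not called as a list (0 up and 2 down of 14 by limma, 0 and 2 adjusted over the list alone, 4 and 3 at an unadjusted p under 0.05, camera adjusted p = 0.953). ECM1 fell from 2.41 ± 0.28 to 1.13 ± 0.0757 FPKM.

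Most genes for cytosolic ribosomal proteins fell by a small amount. Of 34 measured, 27 fell and 0 rose by limma, 28 and 0 when adjusted over the list alone and 30 and 0 at an unadjusted p under 0.05, with a median log2 fold change of −0.21 (camera adjusted p = 2.3e-11, and adjusted p = 0.722 with an estimated correlation). RPS2 went from 416 ± 8.08 to 347 ± 4.76 FPKM (−0.26, SE 0.0358, adjusted p = 0.00346) and RPS3 from 199 ± 0.624 to 163 ± 7.18 (−0.29, SE 0.0431, adjusted p = 0.00481). Genes for ribosome biogenesis and MYC targets were not called as a list (5 up, 2 down of 45, the same adjusted over the list alone, camera adjusted p = 0.987). NOLC1, a nucleolar phosphoprotein whose 3′ UTR holds both TCGGAGA and CCTAAGA, went from 26.1 ± 0.624 to 52.4 ± 0.762 FPKM (0.98, SE 0.0397, adjusted p = 8.8e-05).

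Among lineage genes, 6 of 14 measured members of the lung epithelial list rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0414, and adjusted p = 0.722 with an estimated correlation). The members that moved furthest were FGA, FGB and FGG, plasma proteins made mainly by hepatocytes, followed by the airway mucin gene MUC5B, from 1.00 ± 0.227 to 2.81 ± 0.501 FPKM (log2 fold change 0.93, SE 0.123, adjusted p = 0.00306). The call was lost without sgControl replicate 2 (adjusted p = 0.0526), without sgH2AC19 replicate 3 (0.238) and when all genes above 0 FPKM were tested (0.0942). Epithelial genes moved both ways (8 up, 4 down of 25, the same adjusted over the list alone, camera adjusted p = 0.241, fry adjusted p = 0.0468). KRT18 rose from 302 ± 4.01 to 412 ± 3.27 FPKM and KRT19 fell from 59.9 ± 2.22 to 43.5 ± 2.66. Mesenchymal genes did as well (8 up, 5 down of 29, 8 and 6 adjusted over the list alone, camera adjusted p = 0.554), with COL5A2 up by 0.66 and VIM at −0.33.

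Extracellular matrix and integrin genes were among the most often changed without moving one way, with 13 up and 8 down of 41 (14 and 8 adjusted over the list alone, camera adjusted p = 0.513). The collagen receptor gene ITGA2 went from 91.1 ± 1.57 to 49.0 ± 1.58 FPKM (log2 fold change −0.88, SE 0.0413, adjusted p = 0.000114), and COL12A1 from 4.18 ± 0.185 to 6.89 ± 0.159 (0.61, SE 0.0497, adjusted p = 0.000707). TGF-beta and YAP targets had 11 up and 8 down of 37 (13 and 11 adjusted over the list alone, camera adjusted p = 0.646). NRF2 targets had 9 up and 5 down of 42 (13 and 6 adjusted over the list alone, camera adjusted p = 0.646). Unfolded protein and ATF4 stress genes had 6 up and 9 down of 44 (7 and 12, 0.554), and cholesterol synthesis genes 8 up and 2 down of 33 (9 and 2, 0.383). Mitochondrially encoded genes had 0 up and 1 down of 15 by limma (0 and 1, 0.383), and 2 up and 1 down at an unadjusted p under 0.05. The called gene was MT-RNR1 at −0.35, not called when all genes above 0 FPKM were tested (adjusted p = 0.0899). Nuclear-retained RNAs had 0 up and 1 down of 8 by limma (0 and 1, 0.953), 1 and 1 at an unadjusted p under 0.05, and the called gene was MEG3 at −0.62. In the mesenchymal, NRF2 and cholesterol lists the median was below 0 and the mean and the test were above it. In the 1q21 and nuclear-retained lists the mean was below 0 and the median and the test above it. In the ribosome biogenesis list the mean was above 0 and the median and the test below it.

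Most markers of other cell types were below the level tested. Of 26 endothelial markers 1 was measured, EGFL7, at 6.88 ± 0.384 and 6.82 ± 0.367 FPKM, and of 21 leukocyte markers 1, CD14, at 1.94 ± 0.306 and 2.60 ± 0.516, so neither list could be tested. CD14 was higher when adjusted over its list alone, where it is the 1 gene tested. Of 20 fibroblast and stromal markers 6 were measured and 2 rose, the same number adjusted over the list alone (camera adjusted p = 0.394). COL1A1 rose from 0.641 ± 0.0641 to 1.39 ± 0.124 FPKM and LUM from 2.81 ± 0.299 to 3.97 ± 0.434. COL1A1 passed the filter only through the sgH2AC19 libraries. LUM lost its call in 4 of the 6 fits without 1 library (adjusted p from 0.057 to 0.0697) and when all genes above 0 FPKM were tested (0.0851).

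**Figure D3:**
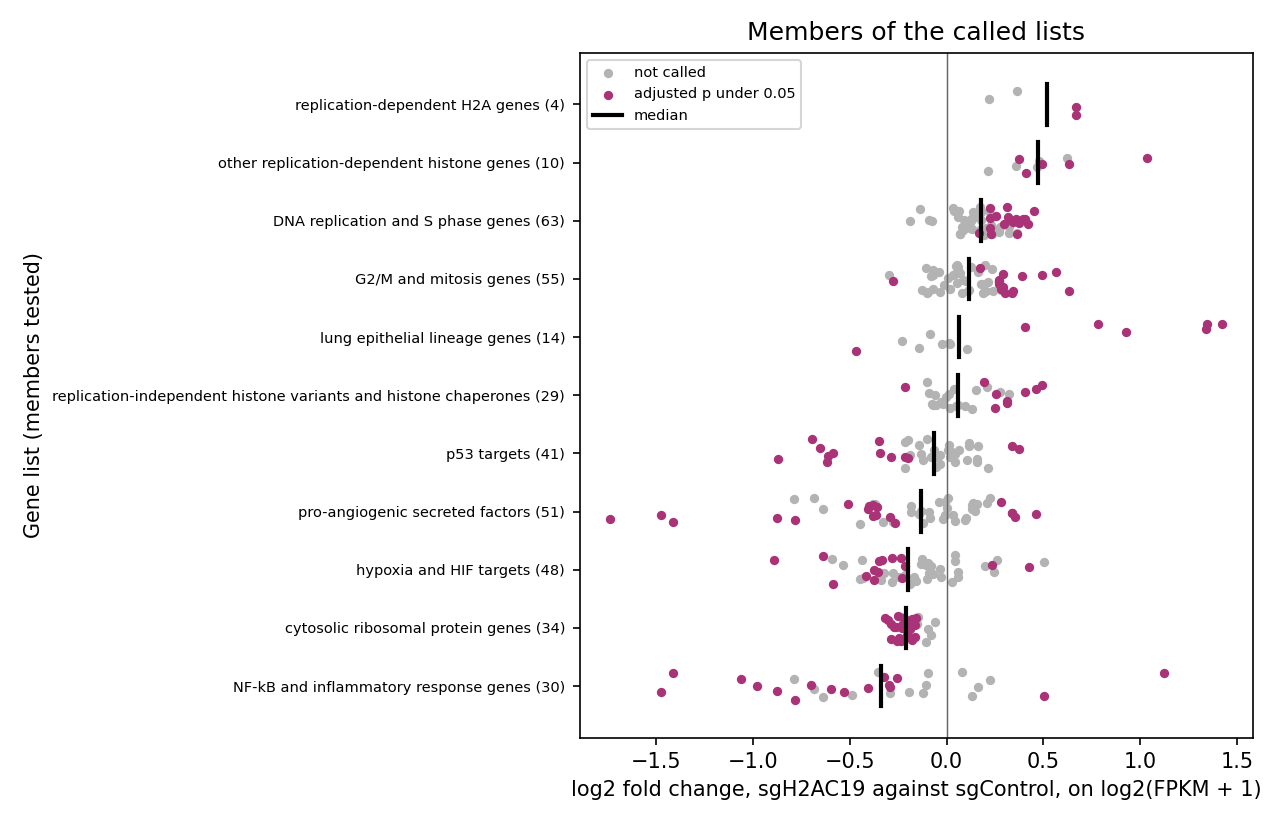
Log2 fold change of sgH2AC19 against sgControl, on the log2(FPKM + 1) scale, for each tested member of the 11 lists called by camera with a preset correlation, one row per list; points are genes, coloured where the adjusted p is below the threshold, and bars are list medians. The median of the ribosomal protein list is −0.21. With an estimated correlation none of the 11 lists is called by camera, with adjusted p-values from 0.722 to 0.844.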

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

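Leaving out genes that hold either 3′ UTR word or have no 3′ UTR to search was chosen after seeing the data; the other alternatives were planned. Of the 97 named genes tested, 84 kept their side of the threshold in every alternative in which they could be tested, and 13 lost their call in at least 1. The sign changed for 1 of them, VEGFA, which was not called in any fit and was at −0.0366 without sgControl replicate 1. None of the 2967 called genes changed sign in any of the 14 refits in which it was tested. Since all of them had separated groups, only the scaling and voom refits could have changed a sign. The number of genes called was 3016 with median-ratio scaling, 2994 with upper-quartile scaling, 3540 with voom, 2923 with a mean of at least 1 FPKM and 2954 with a pseudocount of 0.1. It was 2792 (of 9295 tested) without the genes with a word or with no 3′ UTR. It was 1553 over all genes above 0 FPKM, where 36938 genes share the adjustment, and ran from 1513 without sgControl replicate 2 to 3429 without sgH2AC19 replicate 3, 1965 without sgH2AC19 replicate 2, with 1 library fewer in each. The share of calls that were up was 52.1%, and 58.1%, 59.7% and 59.7% without sgControl replicate 1, 2 or 3. The number of lists called, 11, was 9 over all genes above 0 FPKM, 10 without the genes with a word or with no 3′ UTR, 8 with fry and 0 with an estimated correlation. It ran from 5 without sgControl replicate 2 to 11, with 7 without sgH2AC19 replicate 3. The pro-angiogenic list's adjusted p was 0.722 with an estimated correlation and ran from 0.0175 to 0.112 with 1 library left out; the inhibitor list's fell to 0.0271 with fry. Other than fewer libraries or more genes, the cause was not tested. Same-numbered libraries deviated together only weakly (r of 0.0524, 0.0346 and 0.0602 across genes, which are not independent replicates), so a pairing by number is neither shown nor excluded. Each library correlated best with its own number, a hint from the data and not the design. With the replicate block 2729 genes and 11 lists were called. Apart from voom on the recovered reads, tests planned for a count table were not run, since the table holds FPKM. Depth limits low genes, and no count of reads stands behind a gene listed at 0.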

Other observations

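The tests of the 3′ UTR words for composition and for repression, and leaving out the genes that hold them, were chosen only after those patterns had been seen. The tests of the other strand, of other words in replicate 3 and of near-identical genes also followed patterns already seen, but their bounds were set before their own values were seen. The other splits were planned.

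Several genes outside the lists also fell in sgH2AC19. They were picked after their values had been seen from the 1422 genes called down and were not tested as a group. EGR1, an immediate-early transcription factor gene, was at 12.3 ± 2.30 FPKM in sgControl and 5.54 ± 0.474 in sgH2AC19 (SD, n = 3 each, log2 fold change −1.01, limma adjusted p = 0.00206). The phosphatase gene DUSP5 was at 69.99 ± 11.2 and 37.2 ± 4.69 (−0.89) and DUSP6 at 8.53 ± 0.403 and 5.13 ± 1.26 (−0.66). The cyclin D1 gene CCND1 was at 86.0 ± 3.16 and 54.6 ± 1.54 (−0.65) and HMGA2 at 24.2 ± 0.451 and 12.2 ± 0.798 (−0.94).

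The 225 genes whose 3′ UTR holds TCGGAGA were higher in sgH2AC19 than the rest by 0.1763 (SE 0.0215) on the log2 scale, the top-ranked of 16318 7-base words, by 0.171 to 0.185 for each of the 6 libraries against the other group, and 84 of 1400 genes called up (6%) held it against 1.59% of genes not called. GGAGAAA and TGGAGAA ranked 2 and 3. Among 59967 8-base words TCGGAGAA ranked only 8 (64 genes, shift 0.213), and TGGAGAAA ranked 1 (1103 genes, 0.0518), before AAGGAGAA and ATGGAGAA. These other words lack the core CGGAGA, so part of the rise follows a broader pattern than this word. The 3′ UTR length, base composition or expression level of the genes that hold the site is argued against as the whole cause, since after correction for these TCGGAGA, chosen afresh as the leading word of the even-numbered chromosomes, shifted 125 genes on the odd-numbered ones by 0.165 (SE 0.0286) and ranked 1 among 420 orders of its bases there (z of 6.29 against 3.57 for the next). The leading word of the odd-numbered chromosomes, GGAGAAA, does not hold the 6-base core and shifted 1129 genes on the even-numbered ones by 0.0348 (SE 0.00838), so that direction was left out of this reading after its values were seen. That outcome keeps open repression through a matching seed of a small RNA, stronger in the sgControl libraries. It is a candidate explanation because TCGGAGA is the complement of bases 2 to 8 of TTCTCCGAACGTGTCACGT. From background knowledge, not the labels, this sequence is the sense strand of a negative-control siRNA in common use. For the seed of the other strand the test cannot decide, since both bounds set beforehand were met. Its word TGTCACG moved 337 genes by 0.0305 (SE 0.0133), which is under 0.5 of the first shift but also over 2 SE above 0. Genes with the word only in the coding sequence also lay higher, by 0.104, and an effect of the knockout itself stays open and untested.

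Genes whose 3′ UTR holds CCTAAGA, ranked 2 of 16318 7-base words after CTAAGAA, were lower in sgH2AC19 replicates 1 and 2 but not in replicate 3. Against the sgControl libraries the 1057 such genes were shifted by −0.1035 (SE 0.0091) and −0.108 (SE 0.00925) in replicates 1 and 2 and by 9.5e-05 (SE 0.00843) in replicate 3. VCL and ETS1, 2 genes with the 8-base site chosen after their values had been seen, were at 25.6, 24.6 and 51.8 FPKM and at 10.2, 10.9 and 11.9 FPKM in replicates 1 to 3, against means near 60.9 and 24.3 in sgControl. Of these VCL followed the pattern, whereas ETS1 did not, being about as low in replicate 3 as in replicates 1 and 2. The 3′ UTR length, base composition or expression level of the genes that hold the site is argued against, since the words chosen on odd-numbered and on even-numbered chromosomes, CCTAAGA and CTAAGAA, each ranked 1 among the orders of their bases on the set not used to choose them, and repression through the same seed in replicate 3 by the shift there. A candidate explanation in replicates 1 and 2 is repression through a matching seed of a small RNA, since these words shifted genes on the sets not used to choose them by −0.0784 (SE 0.0106) to −0.109 (SE 0.0142), and the 8-base site CCTAAGAA, ranked 1 of 59967 words, lies once in the coding sequence of H2AC19 (chromosome 1, 149851465 to 149851472, GRCh38) and of H2AC18 (149842340 to 149842347), where 0.824% of the words compared occur. A small RNA with another seed matching the H2AC19 transcript in sgH2AC19 replicate 3 is argued against only for a strong shift, with 0 of its 10 most negative 8-base words in that transcript. Words held by many genes, such as AAAGTGCT (1570 genes, z of −6.52), filled most of those places, so a weaker shift or a rarer word could be missed. Both candidates differ from the labels, which describe guide RNAs and knockout derivatives. Whether any small interfering RNA was present, and whether another factor reads the same word, stays open.

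H2AC19 and H2AC18 are listed at 0 in all 6 libraries. Of 501 protein-coding genes that share at least 95% of their 31-base words with another gene, 73.25% were at 0 in all libraries, against 9.84% of 16110 genes sharing under 5%; H2AC18 shares 100% and H2AC19 97.2%. Reads shared between near-identical genes that were left uncounted are thus a candidate cause of the zeros, but the test set beforehand cannot decide it, because 4 of its 8 named duplicates passed 95%, too few for the 5 it required. Its opposite bound, that at least 50% of those passing be at 1 FPKM or more, was just met by SMN1 (6.51 FPKM) and SMN2 (4.70) against SERF1A (0.00121) and SERF1B (0.751); that 4 genes are too few to decide was settled only after these values were seen, and SMN1 and SMN2 keep 4.12% of words of their own that could hold counted reads. Silence of the gene in both groups, uncounted reads and other causes that were not tested cannot be told apart here. Of the listed replication-dependent histone genes, 4 of 17 H2A genes and 10 of 51 others were measured in these mRNA-seq libraries. The zeros do not show whether sgH2AC19 lost its expression.

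With 10 splits of the 6 libraries a share under 0.05 cannot be reached. The real split called 2967 genes by limma and the highest of the others 0 (1 of 10 splits as large), with 4838 genes at an unadjusted p under 0.05 in the real split and 182 to 535 in the others. For the lists, 3 of 10 splits, the real one included, called at least the 11 lists of the real split, with 13 the most. The camera p of the pro-angiogenic list was 0.0103 in the real split and 0.00638 in the lowest other (2 of 10 as small), and that of the inhibitor list was 0.179 and 0.0195 (9 of 10).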
